A study of Pimephales promelas with 191 samples.

How the data were processed

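Messenger RNA from the livers of adult male fathead minnows (Pimephales promelas), a small freshwater fish kept widely for aquatic toxicology, was measured by RNA sequencing. The labels place the 191 libraries in 16 groups, which cross 4 treatments with collection at 6, 24, 48 and 96 h. The treatments were a control group, metformin at 41 µg/L, guanylurea at 100 µg/L, and a mixture of metformin and guanylurea. Metformin is a biguanide drug against type II diabetes that reaches surface water through sewage, and guanylurea is the product that microbes make from it. Each group held 12 libraries except guanylurea at 24 h, which held 11. Total RNA was extracted with Tri-Reagent and made into libraries with a stranded mRNA kit, per the labels' protocols.

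The authors deposited a table of 26150 genes and a table of 47578 transcripts, each with 1 column per library. The values are expected counts, that is, estimated counts per gene or transcript, deposited as whole numbers: 0 values in both tables were not whole. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2 2.3.5 and RSEM 1.3.1 were used. RSEM shares reads that fit several genes among them by an estimate, so near-identical gene copies have uncertain counts. The genome build, the annotation and whether counting used the strand are not given in the sources used here. The deposited counts were not scaled for depth. Each column name matched 1 library title, and 0 columns were left unused.

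The identifiers of the tables were compared with the RefSeq gene table of the organism (assembly fPimPro1.hap1.1, 64593 genes) by gene number, locus tag, symbol, synonym and accession. Of the 26150 gene identifiers, 0 matched, and of the 47578 transcript identifiers, 0 matched. The files do not pair the identifiers with names. The 36 gene lists fixed beforehand, which covered liver metabolism, endocrine and stress pathways and markers of other cell types, could therefore not be tested, and the rule that named genes by symbol could not be applied. In its place, 4 identifiers are printed: the 2 genes of smallest p in each direction for guanylurea against control averaged over times. Their choice followed the finding that no names matched. All other genes are described as groups defined by their calls.

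Counts were rounded, which changed no value, and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by the TMM method, and dispersions were estimated before a robust quasi-likelihood fit. Unless another tool or a range over alternatives is named, an adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested within a comparison, and a gene is called at an adjusted p under 0.05. Log2 CPM values used a prior count of 2. Medians of gene groups are differences between means of these values, which understate the fitted fold change of genes with low counts.

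The 29 comparisons fall into sets. The treatments were compared with same-time controls, and guanylurea with metformin, in a fit of the 48 libraries of each time (47 at 24 h). Averages over the 4 times, the test of additivity (mixture minus metformin minus guanylurea plus control, on the log2 scale) and the test of a treatment effect that differs between times (an F test on 3 differences) used a fit of all 191 libraries with a mean per group. The control time course used the 48 control libraries. No batch, tank or preparation date is given in the labels. They do not say whether libraries of a group came from separate fish or tanks, so p-values measure the spread between these samples, which may be technical.

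Alternatives fixed before the data were examined were DESeq2 1.42.0, limma 3.58.1 voom with quality weights, DESeq2 size factors in edgeR, no low-count filter, the transcript table, the replicate number as a block, a looser threshold of 0.10, one fit of all libraries, and a fit without libraries of low total or low agreement. Low agreement was a median Pearson correlation of log2 CPM with the rest of the group more than 5 median absolute deviations below the median of all libraries. Bootstrap intervals over libraries used 200 draws. Correlations between treatments that share controls were set beside 200 draws with no effect and beside 20 random splits of the controls into sets of 6 per time. Random regroupings of the libraries numbered 100 for the fits per time and for the controls, and 48 for the fit of all libraries, the real grouping included.

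The fit at 96 h with edgeR, DESeq2 and limma voom, and the edgeR fits of all libraries and of the controls, were tested on simulated data drawn from the real means, library sizes and dispersions, with 200 genes changed by known folds. For guanylurea against control at 96 h, edgeR recovered 10% of genes changed 1.5-fold, 58% of those changed 2-fold and 84% of those changed 4-fold. Of its 84 calls over 16283 genes, 6 were false. For the average over times it recovered 40% at 1.25-fold, 72% at 1.5-fold and 78% at 2-fold. Of those 166 calls over 18022 genes, 21 were false. For additivity it recovered 48% at 1.5-fold. Its 14 false calls stood beside 8, 24, 34 and 50 genes recovered at folds of 1.25, 1.5, 2 and 4. For guanylurea by time it recovered 38% at 2-fold, with 10 false calls beside 0, 2, 19 and 35 genes at these folds. For the controls at 96 h against 6 h it recovered 64% at 2-fold, with 1 false call. In all but the controls, false calls made up a larger share of the calls than the adjusted p threshold is meant to allow. The fits at 6, 24 and 48 h, and DESeq2 and limma voom in the fits of all libraries and of the controls, were not simulated. In these simulations genes vary independently of one another, which real libraries need not do.

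Library totals ran from 12.7 to 28.0 M (mega) counts with a median of 19.5 M. The SE of a log2 difference was derived from the test, as its absolute value over the square root of the F statistic. Its 95% interval used the residual degrees of freedom of the fit alone, so it is approximate. The median half-width of that interval was 0.42 at 96 h for guanylurea against control and 0.23 for the average over times.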

Results

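Liver transcriptomes of male fathead minnows were profiled after 6, 24, 48 and 96 h in control conditions or with metformin, guanylurea or the mixture. The comparisons ask how liver transcripts responded to the drug, to its transformation product and to both. Mean totals per group ran from 17.8 M counts (M, mega) ± 1.88 (SD, n = 12) in metformin at 6 h to 21.3 M ± 3.07 (SD, n = 12) in the mixture at 48 h. Between 18905 and 22376 of the 26150 genes had a count in a library. The 10 most abundant genes took between 27.2% of counts (guanylurea at 96 h, group mean) and 32.2% (mixture at 48 h). No pair of libraries from 1 group agreed within sampling noise, since the smallest chi-square per degree of freedom between such a pair was 36.7. The first principal component of log2 CPM held 7.46% of the variance, and treatment accounted for 3.5% of its spread and collection time for 0.859%. The second component held 5.74%, with 2.47% of its spread by treatment and 7.31% by collection time. Collection time accounted for 21% of the spread on the third component, which held 4.08% of the variance. Agreement with the rest of the group was low in 6 libraries, among them the 96 h control library numbered 2.

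**Figure D1:**
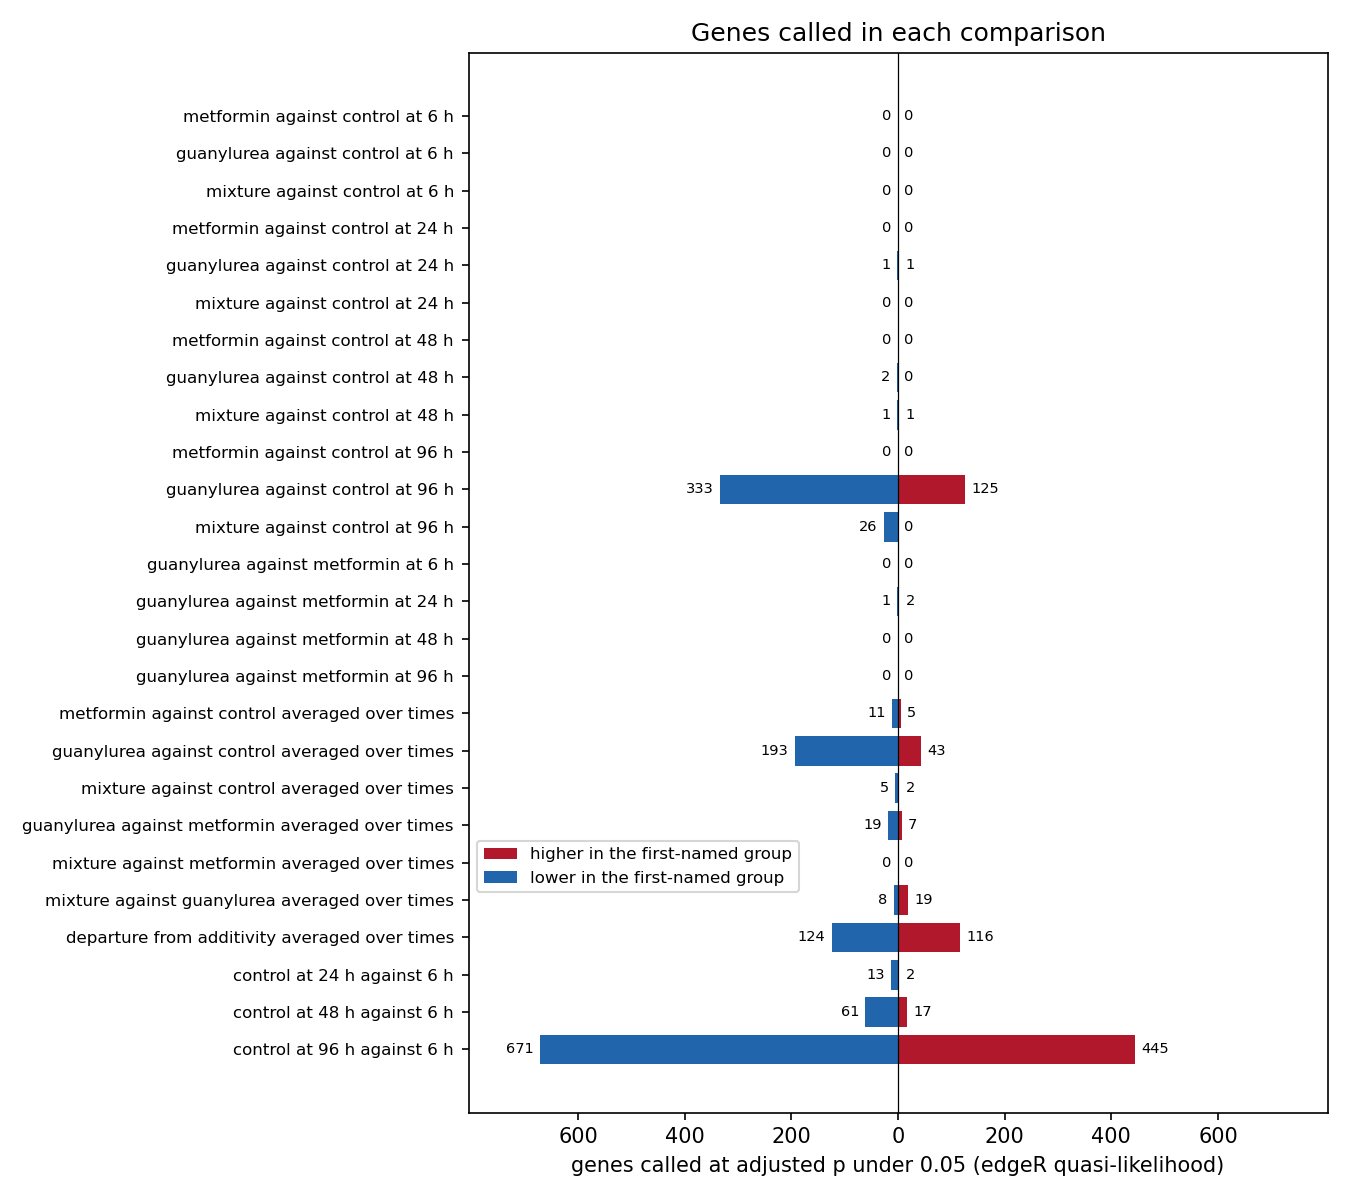
Number of genes called at an adjusted p under 0.05 in each comparison, with genes higher in the first-named group as bars to the right and genes lower in it as bars to the left. The 1116 genes called in controls at 96 h against 6 h and the 458 called for guanylurea at 96 h stand beside 0 calls for metformin at each time.

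The control time course shows what differed between collection times with no test compound. Expression changed in 1116 of 16322 genes between 6 and 96 h, of which 445 rose and 671 fell. The median change of a called gene was 0.66 on the log2 scale, and 295 called genes changed by 2-fold or more. The 445 genes that rose stood at a median log2 change of 0.73 at 96 h (quartiles 0.54 to 0.98), and at 0.31 at 24 h and 0.21 at 48 h. The 671 genes that fell stood at −0.55 at 96 h (quartiles −0.71 to −0.44), and at −0.27 at 24 h and −0.26 at 48 h. The falling genes were the more abundant, with a median log2 CPM of 3.83 against 2.33 for the rising genes and 2.17 for all tested genes. At 24 h 15 genes passed, 2 higher and 13 lower, and at 48 h 78 passed, 17 higher and 61 lower. All 3 comparisons share the 6 h controls, which contributes to their likeness. Collection time is also a collection occasion, so hours of exposure, time of day and handling are not separable. Without the 96 h control libraries numbered 2 and 4, which had the lowest agreement of that group, 735 genes passed at 96 h.

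The same 1116 genes were followed in the exposed groups, each against its own 6 h libraries. In the 445 genes that rose in controls, the median change at 96 h was 0.27 with metformin, 0.06 with guanylurea and 0.26 with the mixture. In the 671 genes that fell, the medians were −0.33, −0.22 and −0.36. The direction matched that of the controls in 90.3% of the 1116 genes with metformin, 74.6% with guanylurea and 88.1% with the mixture. Because the genes were selected in controls, the control change is overstated relative to the others. In their own right, 796 genes passed between 6 and 96 h with metformin, 348 with guanylurea and 1305 with the mixture, against 1795 in controls in the same fit of all libraries. These 4 tests were added after the control result was seen.

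**Figure D2:**
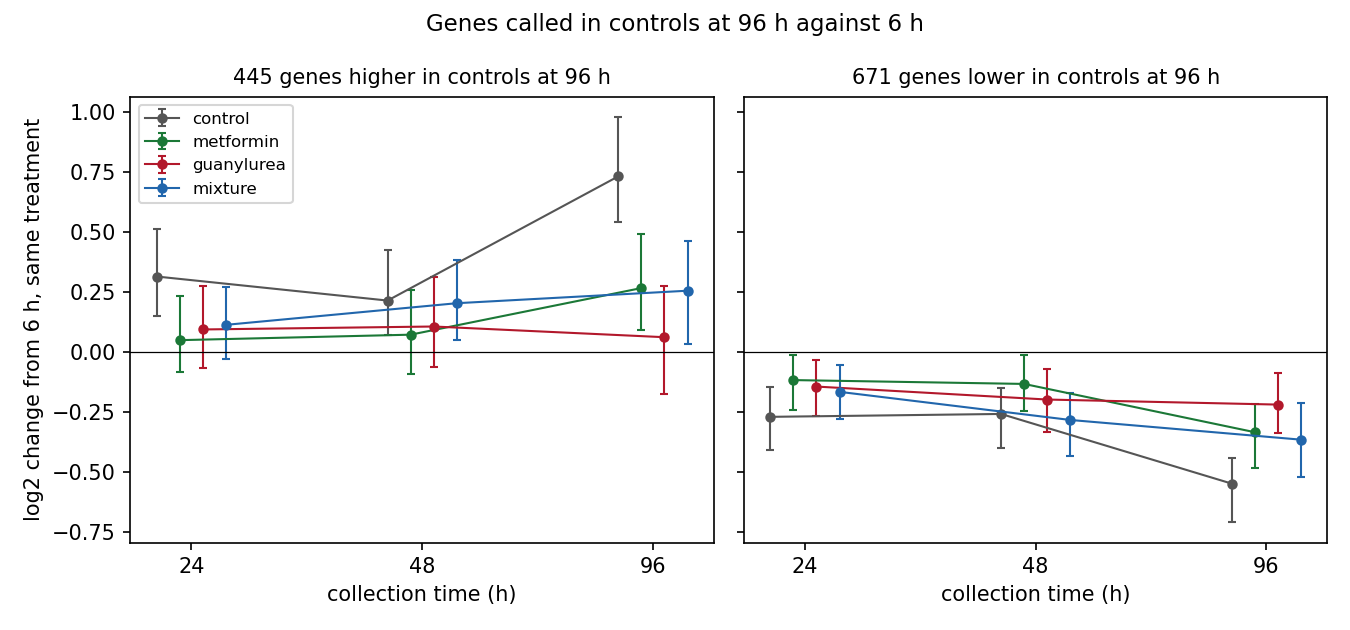
Median log2 change from 6 h, with quartiles as bars, of the 445 genes higher (left) and the 671 genes lower (right) in controls at 96 h, in each treatment against its own 6 h libraries over collection time in hours. The control points lie farthest from 0 at 96 h, at 0.73 and −0.55, and the guanylurea points nearest to 0, at 0.06 and −0.22.

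With guanylurea at 100 µg/L, most genes that differed from control averaged over the 4 times were lower. Of 18145 genes, 236 changed, and 193 of them were lower and 43 higher. Changes were mostly below 2-fold, with a median size of 0.44 on the log2 scale and 57 genes at 2-fold or more. The 193 lower genes had median log2 differences from same-time controls of −0.37 at 6 h, −0.37 at 24 h, −0.34 at 48 h and −0.37 at 96 h. The 43 higher genes stood at 0.31, 0.47, 0.37 and 0.62. Selection on the average of these same libraries favours genes that differ at every time, so the medians are no separate test of a response at each time. For 168 of the 236 genes the group medians differed in the called direction at all 4 times. In the same 193 genes the average median was −0.17 with metformin and −0.14 with the mixture, values that include the chance deviations of the shared controls. Leaving out 96 h left 95 genes called and leaving out 24 h left 136. In random regroupings of the same libraries the averaged comparison called a median of 10 genes. Of 48 groupings, the real one included, 2 called 236 or more (highest other 406).

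The gene FMg021927 had the smallest p of all genes for guanylurea, at a log2 fold change of −1.64 (SE 0.22, adjusted p = 1.07e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It is abundant in these livers, with a mean log2 CPM of 10.11. Its CPM values were 1112 ± 426 in controls and 364 ± 314 with guanylurea at 6 h (SD, n = 12 each). At 24 h they were 1672 ± 797 (SD, n = 12) and 431 ± 292 (SD, n = 11). At 48 h they were 1867 ± 1770 and 621 ± 464, and at 96 h 1009 ± 476 and 383 ± 304 (SD, n = 12 each). The guanylurea libraries below the median of the control log2 values numbered 11 of 12 at 6 h, 11 of 11 at 24 h, 10 of 12 at 48 h and 11 of 12 at 96 h. The size of the difference varied with the replicate number of the libraries, from a mean over times of −3 to −0.19 across the 12 numbers. That mean was below 0 in 12 of 12, but numbers 9 and 11 were lower at only 2 of 4 times. Numbers 2 and 7 were lower at 3 of 4 times, and the others at every time. In the separate fits per time it passed at 24 h alone (log2 fold change −1.96, adjusted p = 0.0219), with adjusted p = 0.465 at 6 h, 0.496 at 48 h and 0.065 at 96 h in the same test. With metformin its average log2 difference from control was −0.09 (95% interval −0.51 to 0.34) and with the mixture −0.19 (−0.62 to 0.24). The mixture libraries numbered 12 held 7923.2 CPM at 6 h and 4302.4 CPM at 96 h, far above the other mixture libraries of those times. They raise the mixture average, while a control library of 7190.3 CPM (number 12 at 48 h) lowers it. Over 11 alternatives the mixture average ran from −0.41 to −0.05 and never passed the threshold. FMg011947 was also lower with guanylurea, by an average of −0.65 (SE 0.10, adjusted p = 1.59e-06), and lay below the control median in 9 of 12, 8 of 11, 12 of 12 and 10 of 12 libraries over the 4 times. Among the higher genes, FMg003228 averaged 1.17 (SE 0.26, adjusted p = 0.00405) and lay above the control median in 10 of 12, 8 of 11, 10 of 12 and 9 of 12 libraries. Leaving out 48 h or 96 h ended that call, with adjusted p = 0.0975 and 0.0567. FMg007005 averaged 2.37 (SE 0.495, adjusted p = 0.00186), but its median at 24 h with guanylurea was 0.143 CPM and its highest library held 103.5. It lay above the control median in 6 of 12, 6 of 11, 7 of 12 and 3 of 12 libraries, so that average rests on few libraries, and limma voom gave it 0.54 (adjusted p = 0.692).

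**Figure D3:**
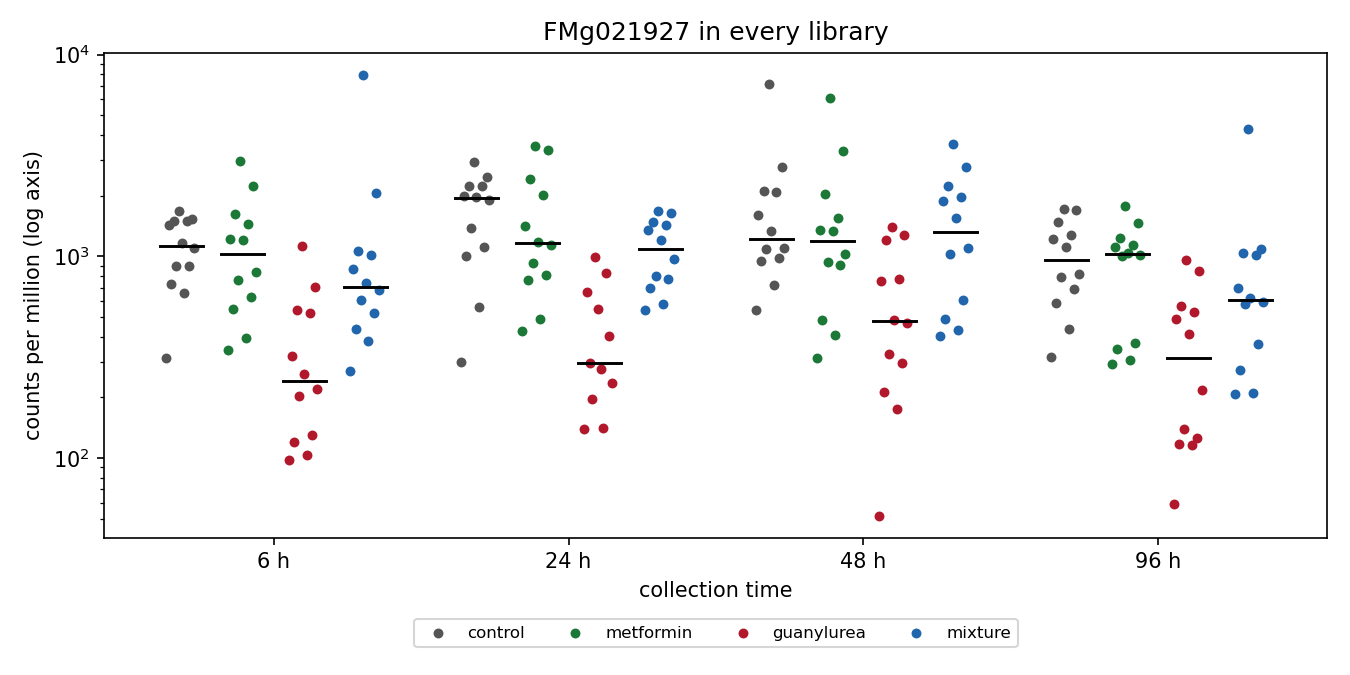
CPM (count scaled to library size) of FMg021927 on a log axis in every library, by collection time and treatment, with the group median as a black line. The guanylurea medians lie below the medians of the other 3 treatments at each time. Scaled without the low-count filter, as in the text, they were 243.1 at 6 h, 297 at 24 h, 480.9 at 48 h and 315.2 at 96 h. The plotted values were scaled after that filter and differ slightly.

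**Figure D4:**
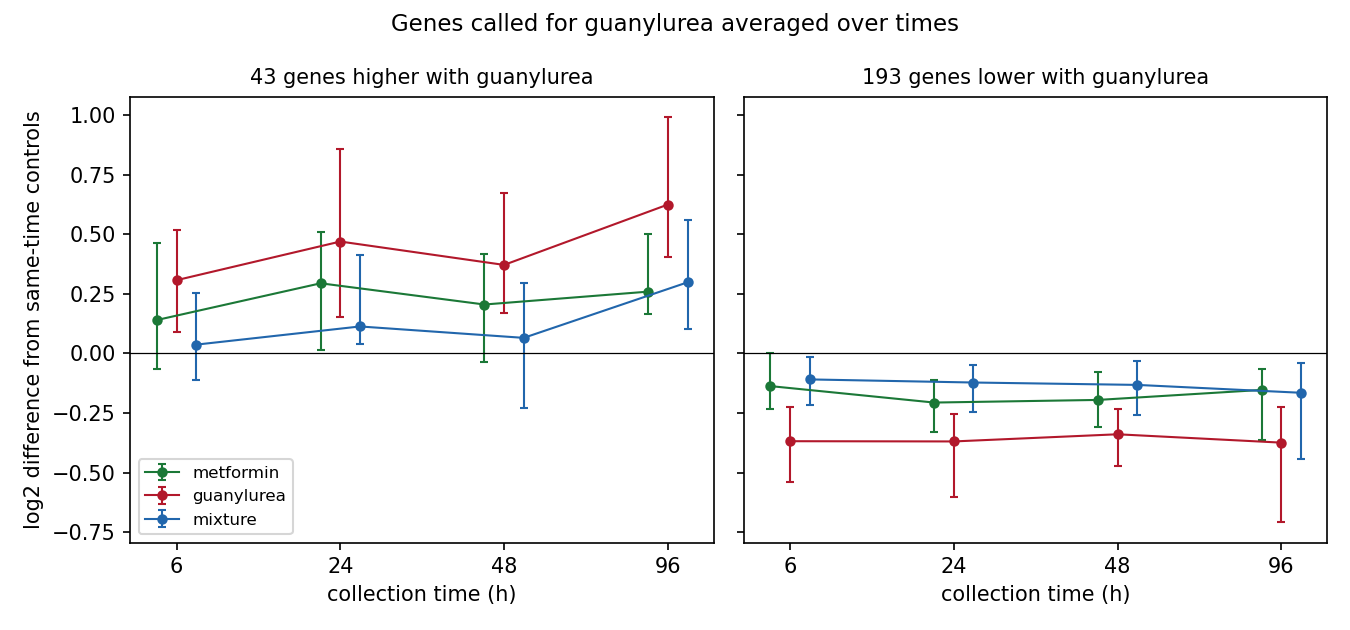
Median log2 difference from same-time controls, with quartiles as bars, of the 43 genes higher (left) and the 193 genes lower (right) with guanylurea averaged over times, for each treatment over collection time in hours. The guanylurea points of the 193 lower genes, which were selected on the average of these times, lie between −0.37 and −0.34.

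Most same-time calls for guanylurea came at 96 h. Expression changed in 458 of 16436 genes, 125 higher and 333 lower, with a median size of 1.2 on the log2 scale and 279 genes at 2-fold or more. The 333 lower genes had a median log2 difference of −0.89 at 96 h, but 0.09 at 6 h, −0.09 at 24 h and 0.07 at 48 h. At 96 h these 333 genes also lay below controls with metformin (−0.43) and the mixture (−0.55). The genes were selected against the same control libraries, so a chance deviation of those controls enters these values too. The 125 higher genes stood at 0.82 at 96 h and at −0.03, 0.15 and 0.04 before. Selection at 96 h by itself favours larger medians at that time than at the others. Between 6 and 96 h the 333 genes moved by a median of 0.70 in controls, 0.12 with metformin, 0.09 with the mixture and −0.33 with guanylurea. The 125 genes moved by −0.44, −0.03, 0.05 and 0.37. Among genes tested in both comparisons, 130 of 326 lower genes were also called as rising in controls from 6 to 96 h, and 39 of 121 higher genes as falling. Both comparisons share the 96 h controls, which pushes such genes to opposite sides. At the other times edgeR called 0 genes at 6 h, 2 at 24 h and 2 at 48 h, with 958, 1390 and 1019 genes at an unadjusted p under 0.05 where 805.6, 820.8 and 830.4 would be expected. DESeq2 called 3 genes at 6 h and limma voom 0. The count of 458 at 96 h fell to 202 without the control library numbered 2, to 221 without number 4 and to 33 without both, and limma voom with quality weights called 26.

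Metformin at 41 µg/L gave 0 called genes at each time against same-time controls in edgeR fits of single times, while 1 fit of all libraries called 11, 7, 6 and 130 genes at 6, 24, 48 and 96 h. In the fits of single times, genes at an unadjusted p under 0.05 numbered 930, 1192, 933 and 1342, where 805.6, 820.8, 830.4 and 821.8 would be expected. DESeq2 called 2, 2, 2 and 0 genes, and limma voom 0 at each time. The 95% interval of the difference lay within 2-fold for 77.7%, 77.9%, 77.5% and 75.5% of tested genes. Averaged over the 4 times, 16 of 18145 genes changed, 5 higher and 11 lower. The median fitted size was 1.39 on the log2 scale, with 11 of 16 genes at 2-fold or more. Between means of log2 CPM, the 5 higher genes had a median difference of 0.59 and the 11 lower genes of −0.49. Group medians of 6 of the 16 genes differed in the called direction at all 4 times, and 6 of the 16 lay below a mean of 1 CPM. Random regroupings called a median of 12 genes in this comparison, and 19 of 48 groupings, the real one included, called 16 or more.

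The mixture gave 26 called genes at 96 h, and all 26 were lower than in controls. The median fitted size was 2.51 on the log2 scale, and 26 of 26 lay at 2-fold or more. Between means of log2 CPM, which understate changes of low genes, the median difference was −1.02 with the mixture, −1.19 with guanylurea and −0.57 with metformin, against the same 12 control libraries. They were expressed at low levels, with a median log2 CPM of 0.23. At 6 and 24 h edgeR called 0 genes, with 570 and 547 genes at an unadjusted p under 0.05, DESeq2 called 1 and 0, and limma voom 0 and 0. At 48 h 2 genes passed. Without the 96 h control library numbered 2 edgeR called 0 genes at 96 h (1464 at an unadjusted p under 0.05), and with all libraries limma voom called 0 (1291). Averaged over times, 7 genes passed, 2 higher and 5 lower, fewer than the median of 18 in random regroupings.

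Guanylurea differs from metformin by the loss of both methyl groups and by a carbonyl in place of an imino group. The concentrations also differed, at 41 µg/L metformin and 100 µg/L guanylurea, so the compounds were not compared at matched doses. Averaged over times, 26 of 18145 genes differed between guanylurea and metformin, 19 lower and 7 higher with guanylurea. FMg021927 showed the difference of smallest p, at −1.56 on the log2 scale (95% interval −2 to −1.12, adjusted p = 8.74e-07). FMg011947 differed by −0.51 (−0.70 to −0.32, adjusted p = 0.0012). Both genes were selected on the same guanylurea libraries against control, which favours a difference from metformin too. FMg003228 did not pass, with a difference of 0.17 (−0.32 to 0.66, adjusted p = 0.915), and neither did FMg007005, at 1.93 (0.97 to 2.88, adjusted p = 0.0533). For 91.6% of genes the 95% interval of the averaged difference lay within 2-fold, and for 76.3% within 1.5-fold. At single times edgeR called 0, 3, 0 and 0 genes at 6, 24, 48 and 96 h, with 506, 727, 697 and 1603 genes at an unadjusted p under 0.05. DESeq2 called 0, 12, 0 and 6 genes, and limma voom 0 at each time. The averaged contrast called a median of 14 genes in random regroupings, and 15 of 48 groupings, the real one included, called 26 or more.

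FMg021927 and FMg011947 stood nearer to control in the mixture than with guanylurea alone. Both were picked for low values in these same guanylurea libraries, which favours such a difference, so the values below are no separate test. FMg021927 was higher in the mixture than with guanylurea by 1.45 on the log2 scale (95% interval 1.02 to 1.89, adjusted p = 1.03e-05), and FMg011947 by 0.47 (0.28 to 0.66, adjusted p = 0.00868). In all, 27 genes differed between the mixture and guanylurea averaged over times, 19 higher and 8 lower in the mixture. Random regroupings called a median of 19, and 19 of 48 groupings, the real one included, called 27 or more. Limma voom called 387 genes, and edgeR 98 without the libraries of low agreement. Between the mixture and metformin edgeR called 0 genes, with 1706 at an unadjusted p under 0.05, while DESeq2 called 5 and limma voom 3.

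The 2-by-2 test of additivity called 240 of 18145 genes averaged over times. In the 116 genes above the additive expectation, the median log2 difference from control was −0.21 with metformin, −0.35 with guanylurea and −0.08 with the mixture. In the 124 genes below it, the medians were 0.22, 0.22 and 0.01. These medians follow from the selection, since genes chosen for this contrast tend to have the single compounds on 1 side and the mixture near control. The control libraries enter each of these differences, so a chance deviation of controls moves the single compounds together. FMg021927 departed from additivity by 1.54 (95% interval 0.93 to 2.15, adjusted p = 0.0053), FMg011947 by 0.61 (0.34 to 0.87, adjusted p = 0.0108) and FMg003228 by −1.48 (−2.19 to −0.78, adjusted p = 0.0184). These named genes were selected on guanylurea against control, which enters this contrast and favours such departures. Limma voom called 1381 genes in this test, 211 of them among the 240.

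Treatment effects were tested for a difference between times with an F test. It called 405 genes for guanylurea, 197 for the mixture and 57 for metformin. Random regroupings of the libraries called medians of 111, 91 and 92 genes in these tests, so the metformin count lay below that of random groupings. The same contrast in limma voom with quality weights called 1, 0 and 0 genes, with 1272 and 749 genes at an unadjusted p under 0.05 for the mixture and metformin.

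Responses of the 3 treatments were alike to the extent that shared controls produce. Over 18145 genes, the correlation of averaged log2 fold changes was 0.504 between metformin and guanylurea, where groups with no effect gave 0.513 (95% range 0.31 to 0.685). It was 0.416 between metformin and the mixture, and 0.411 between guanylurea and the mixture, where no effect gave 0.515 and 0.512. With the controls split so that each treatment had its own, the values were 0.0894, −0.0337 and 0.00394. The covariances minus those with no effect were 0.00322, −0.00208 and −0.000766. These are correlations across genes, which are not independent replicates.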

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

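The test of the control side of the gap at 96 h was chosen after the result was seen, as were the contrasts against the mean of metformin and mixture, the left-out libraries at 96 h and the left-out times. Effects of a treatment that differed between times came up for a closer look because the difference itself passed a test, in 405 genes for guanylurea, 197 for the mixture and 57 for metformin. Likewise, the guanylurea effect differed with and without metformin in 240 genes averaged over times, and for FMg021927 by 1.54 on the log2 scale.

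Guanylurea against control at 96 h called 458 genes, and 2 of 100 splits of the same libraries, the real one included, called as many (highest other 953). Few splits reached the count, but a random split exceeded it. The splits did not take the replicate numbers into account, and most calls were lost with the number as a block. They therefore cannot exclude chance or an unlabelled structure of the samples. That the 96 h control libraries stood apart may account for part of the pattern. Seen from the mean of metformin and mixture, the controls made up a share of 0.537 of the gap (95% bootstrap interval 0.39 to 0.697). Genes selected by chance on guanylurea minus control give a share near 0.5 where the groups spread alike. The share therefore cannot tell the control side and the guanylurea side apart. Over all genes at 96 h, controls against that mean called 84 genes and guanylurea against it 9, with 1737 and 1771 at an unadjusted p under 0.05, which puts more calls on the control side. The slope of mixture minus metformin on guanylurea minus control was 0.114 (−0.0997 to 0.288). A guanylurea effect of equal size with and without metformin predicts a slope near 1, and 0.5 or more was the cutoff set beforehand. The genes were selected on guanylurea minus control, which lowers the slope, and the interval kept those libraries as observed. Controls that alone differ also give a slope near 0 (−0.00312 in simulated data). The slope therefore does not decide whether the effect was of equal size. Without the 96 h control libraries numbered 2 and 4 the comparison called 33 genes, and a guanylurea effect seen without metformin stays open as a hypothesis.

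Guanylurea against control averaged over times called 236 genes, and 2 of 48 splits, the real one included, called as many, the highest other 406. Few splits reached the count, but a random split exceeded it, and the splits ignored the replicate numbers. Chance is therefore not excluded. The controls made up a share of 0.41 of the gap (0.304 to 0.53), which leaves open how much of the set reflects the controls. The share that chance selection gives, as described for 96 h, lies within that interval. Over all genes averaged over times, controls against the mean of metformin and mixture called 35 genes and guanylurea against it 59. At an unadjusted p under 0.05 these contrasts held 1498 and 1898 genes, so unlike at 96 h more calls lay on the guanylurea side. The slope of mixture minus metformin on guanylurea minus control was 0.0184 (−0.159 to 0.193). Selection of the genes on guanylurea minus control lowers this slope too, and controls that alone differ would also give a low slope. It therefore does not decide whether the effect was of the same size in the presence of metformin. FMg021927 averaged −1.64 with guanylurea against control and −1.56 against metformin, with the guanylurea libraries in common. In the mixture, which also held guanylurea, it averaged −0.19 against control, and its departure from additivity of 1.54 measures that contrast. Mixture libraries of 7923.2 CPM at 6 h and 4302.4 CPM at 96 h raise that average, and a control library of 7190.3 CPM at 48 h lowers it. Among 11 alternatives it reached −0.41. The replicate number accounted for 52.9% of the spread of FMg021927 with guanylurea and 50.5% with the mixture, against 29.9% in controls and 28% with metformin. A response to guanylurea itself and an unlabelled difference of the guanylurea libraries cannot be told apart. A biological difference between the exposures remains a hypothesis found and tested on the same libraries.

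The test of additivity called 240 genes, and 1 of 48 splits, the real one, called as many, with 83 in the highest other. Guanylurea by time called 405 genes, reached by 1 of 48 splits (highest other 291). No random split reached either count, but the splits did not take the replicate numbers into account. The mixture by time called 197 genes, reached by 3 of 48 splits (highest other 268), and metformin by time called 57, reached by 36 of 48 (highest other 286), so chance cannot be excluded for either.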

How the results depend on the processing

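The settings without single times, without both 96 h control libraries of lowest agreement and without each 96 h control library in turn, and the test of FMg021927 by number, were chosen after seeing the data, and all others were fixed before the data were examined. Of the counts of called genes, 158 stayed within 1.5 times and 160 did not. Of the values of named genes, 225 kept direction and side of the threshold, 7 were no longer past it, 2 came to pass it and 7 changed sign. Those 7 were differences of FMg021927 from control that passed the threshold in neither fit. The cause was not tested except where libraries were left out. With metformin at 6 h the log2 difference of 0.08 became −0.32 in limma voom, and with the mixture at 6 h 0.30 became −0.54. Without low-agreement libraries, −0.20 with metformin at 48 h became 0.24 and −0.32 with the mixture became 0.11. That setting leaves out the 48 h control library numbered 12, which held 7190.3 CPM of this gene, the most among the 48 h controls. FMg021927 stayed past the threshold for guanylurea averaged over times in 11 of 11 alternatives, between −1.94 and −1.53, with adjusted p from 2.56e-12 to 0.00024 in those fits, DESeq2 and limma voom included. DESeq2 size factors in edgeR moved no count by over 1.5 times. Tests of gene lists were not run, because the identifiers have no names. Counts below are genes called, and for those that moved the cause was not tested except where fewer genes or libraries entered. Where a count is 0, edgeR or the named tool gave the number in brackets at an unadjusted p under 0.05, and the counts of the other tools stand in the same part or with the comparison.

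DESeq2 called 2, 2 and 2 genes for metformin at 6, 24 and 48 h, 3, 31, 6 and 736 for guanylurea at the 4 times, 1 and 43 for the mixture at 6 and 96 h, and 12 and 6 for guanylurea against metformin at 24 and 96 h. Averaged, it called 38 for metformin, 15 for the mixture, 47 for guanylurea against metformin, 5 for mixture against metformin, 55 for mixture against guanylurea and 398 for additivity, and in controls 116 at 24 h and 204 at 48 h. Limma voom with quality weights called 1, 1 and 26 for guanylurea at 24, 48 and 96 h, 0 for the mixture at 48 h (1540) and 96 h (1291), and 0 for guanylurea against metformin at 24 h (614). Averaged, it called 5 for metformin, 409 for guanylurea (168 shared with edgeR's 236), 0 for the mixture (934), 8 for guanylurea against metformin, 3 for mixture against metformin, 387 for mixture against guanylurea and 1381 for additivity. By time it called 0 for metformin (749), 1 for guanylurea and 0 for the mixture (1272), and 23 in controls at 24 h.

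With no low-count filter, metformin gave 10 and 4 at 6 and 96 h, guanylurea 9, 66 and 733 at 6, 24 and 96 h, the mixture 6, 2 and 180 at 6, 24 and 96 h, and guanylurea against metformin 1 and 72 at 6 and 24 h. The averages gave 34 for metformin, 30 for the mixture and 46 for mixture against guanylurea, the tests by time 239, 979 and 445 for metformin, guanylurea and mixture, and controls at 24 h 29. One fit of all libraries gave 11, 7, 6 and 130 for metformin over the 4 times, 13, 44, 72 and 852 for guanylurea, 6, 2, 23 and 331 for the mixture, 1, 62, 12 and 9 for guanylurea against metformin, and 98, 241 and 1795 for controls at 24, 48 and 96 h.

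At an adjusted p under 0.10, guanylurea gave 9, 4 and 1027 at 24, 48 and 96 h, metformin 5 and the mixture 54 at 96 h, and guanylurea against metformin 10 and 2 at 24 and 96 h. The averages gave 59, 458 and 23 for metformin, guanylurea and mixture, 63 for guanylurea against metformin, 4 for mixture against metformin, 75 for mixture against guanylurea and 659 for additivity. The tests by time gave 124, 635 and 300, and controls 69, 177 and 1988.

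In the transcript table, where transcripts in place of genes are counted, guanylurea gave 0 at 24 h (1338), 0 at 48 h (871) and 161 at 96 h, the mixture 0 at 48 h (1251) and 0 at 96 h (1577), and guanylurea against metformin 0 at 24 h (716). The averages gave 172, 414 and 160, then 206 for guanylurea against metformin, 160 for mixture against metformin, 227 for mixture against guanylurea and 381 for additivity. The tests by time gave 412, 696 and 637, and controls at 96 h 730.

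Replicate numbers are shared by the groups, but do not pair the libraries: the mean correlation of deviations between libraries of 1 number was 0.0102, against −0.000746 for other numbers, and 21 of 191 libraries correlated best with their own number. A residual component holding 5.82% of the variance nevertheless had 26.1% of its spread between numbers, where permuted numbers gave a mean of 6.30% (p = 1e-04, the smallest that 10000 permutations can give). Of the principal components of log2 CPM, the number accounted for 21.1% of the spread on the second, 15% on the third and 14.2% on component 4, more than treatment did on each. With the replicate number as a block, guanylurea gave 1 at 24 h, 0 at 48 h (839) and 12 at 96 h, the mixture 1 at 48 h and 0 at 96 h (1263), and guanylurea against metformin 0 at 24 h (642). The averages gave 0 for metformin (1966), 0 for the mixture (1047), 9 for guanylurea against metformin and 2 for mixture against metformin, while guanylurea averaged gave 217. The tests by time gave 0 (1108), 184 and 15. For FMg021927 the block gave −0.0084 with metformin and −0.12 with the mixture at 6 h, and 0.068 with metformin at 96 h, each of the other sign than without it. The number accounted for 52.9% of the spread of FMg021927 around its group means with guanylurea and 50.5% with the mixture, where permuted numbers gave means of 25.7% and 25% (permutation p = 0.005 and 0.0052, adjusted p over 4 treatments 0.01 each). It accounted for 29.9% in controls and 28% with metformin (p = 0.28 and 0.35, adjusted p 0.35 each). The random splits of the libraries did not take the replicate numbers into account.

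Without the 6 libraries of low agreement, guanylurea gave 272 at 96 h, the mixture 0 at 48 h (1426) and 0 at 96 h (1357), and guanylurea against metformin 0 at 24 h (633). The averages gave 9 for metformin, 7 for mixture against metformin and 98 for mixture against guanylurea, and the mixture by time 65. Without both 96 h control libraries of lowest agreement, guanylurea gave 33 and the mixture 0 (1343) at 96 h, metformin averaged 3 and controls at 96 h 735. Leaving out each 96 h control library in turn gave 202 (without number 2) to 705 (without number 10) for guanylurea at 96 h, 0 (without number 2, 1464) to 58 (without number 10) for the mixture, 0 to 1 for metformin and 811 to 1296 for controls. Guanylurea gave 221 and the mixture 12 without number 4.

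Averages without 6 h gave 6 for metformin and 14 for the mixture. Those without 24 h gave 9, 136 and 22 for metformin, guanylurea and mixture, without 48 h 3 for metformin, and without 96 h 6 for metformin and 95 for guanylurea. With split controls the correlations between treatments were 0.0894, −0.0337 and 0.00394. Totals of 12.7 to 28.0 M counts limit the precision for genes of low expression.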

Other observations

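The tests of whether the control time change was shared by each exposed group were chosen after the control result was seen, as were the tests of 96 h against 6 h within each exposed group.

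Changes between 6 and 96 h were compared between groups over the genes called in 1 of them. Over the 796 genes called with metformin, the slope on the metformin change was 0.555 in controls, 0.507 with guanylurea and 0.591 with the mixture, with the same sign in 92.5%, 93.8% and 94.6% of genes. Over the 1305 genes called with the mixture, it was 0.486 in controls, 0.597 with metformin and 0.526 with guanylurea, with the same sign in 88.7%, 94.6% and 93.3%. Over the 348 genes called with guanylurea, it was 0.178 in controls, 0.538 with metformin and 0.599 with the mixture, with the same sign in 77.3%, 94% and 92%. Over the 1795 genes called in controls, it was 0.391 with metformin (95% bootstrap interval 0.213 to 0.588), 0.0887 with guanylurea (−0.116 to 0.237) and 0.345 with the mixture (0.192 to 0.489). The control and guanylurea changes thus had the lowest slopes on each other, while the controls were no farther from metformin than guanylurea was over the genes called with metformin. These slopes are across genes, which are not independent replicates.

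The controls at 96 h against 6 h called 1116 genes, and 1 of 100 splits, the real one, called as many, with 419 in the highest other. No random split reached the count, but the splits did not take the replicate numbers into account. Over those genes the slope of the metformin change on the control change was 0.424 (95% bootstrap interval 0.198 to 0.63) and that of the mixture 0.39 (0.197 to 0.57). Selection of the genes in controls lowers all 3 slopes. A fully shared change had a slope of 0.871 in simulated data, but over 102 called genes with changes up to 4-fold that varied independently. The real genes are more numerous and mostly changed by less than 2-fold, so how far selection lowers their slopes was not measured. A fully and a partly shared change both stay open. The guanylurea slope was 0.112 (−0.0659 to 0.278), the lowest of the 3 and below 0.5 with its whole interval. For the same reason it does not decide whether the time change was of equal size in that group. Nor does this slope exclude a smaller shared change, as 74.6% of the genes had the same sign and the 671 genes that fell in controls had a median of −0.22 with guanylurea. The 96 h control libraries numbered 2 and 4 may contribute, as 735 genes passed without them. Time of day, handling and time in the test system are confounded with collection time and cannot be separated here.

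The 96 h control library numbered 2 held 168 genes at more than 16-fold above their median over all libraries, the highest number of any library, and number 4 held 106, where the median library held 38. Their median correlations with the rest of their group were 0.931 and 0.938, against a median of 0.956 over all libraries.

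Splits of the same libraries set the remaining counts in context. At 48 h against 6 h the controls called 78 genes, reached by 2 of 100 splits (highest other 85). The mixture at 96 h called 26, reached by 4 of 100 (highest other 51). Few splits reached these counts, but a random split exceeded each of them. The splits ignored the replicate numbers, and the shares make no allowance for the number of comparisons. The mixture count also fell to 0 without the 96 h control library numbered 2. Chance is therefore not excluded for either comparison. Nor can chance be excluded for the controls at 24 h with 15 genes, reached by 7 of 100 splits (highest other 72). The same holds for guanylurea at 24 h with 2 genes (14 of 100, highest other 15), guanylurea at 48 h with 2 (8 of 100, highest other 14), the mixture at 48 h with 2 (9 of 100, highest other 7), and guanylurea against metformin at 24 h with 3 (8 of 100, highest other 27). It holds for the averages too: metformin with 16 genes (19 of 48, highest other 498), the mixture with 7 (39 of 48, highest other 176), guanylurea against metformin with 26 (15 of 48, highest other 113), and mixture against guanylurea with 27 (19 of 48, highest other 369). Where edgeR called 0 genes, every split called as many. These were mixture against metformin averaged (48 of 48, highest other 246), and, each with 100 of 100, metformin at 6 h (highest other 148), 24 h (24), 48 h (16) and 96 h (126), guanylurea at 6 h (3), the mixture at 6 h (4) and 24 h (20), and guanylurea against metformin at 6 h (874), 48 h (8) and 96 h (191). Their counts at an unadjusted p under 0.05 and by DESeq2 and limma voom stand with each comparison above. Some of these splits called several times the real count, which may reflect a structure of the samples or genes that vary together between samples, and these were not told apart by a test.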
